A study of Mus musculus with 22 samples.

How the data were processed

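Total RNA of testis, brain and muscle from C57BL/6J mice, either wild type or mutant in Sgms1, was profiled on 22 Illumina bead arrays. Sgms1 encodes sphingomyelin synthase 1, the Golgi enzyme that makes sphingomyelin and diacylglycerol from ceramide and phosphatidylcholine. Per the labels, RNA was extracted with Trizol, cleaned on RNeasy columns and amplified to biotinylated cRNA with the Ambion MessageAmp kit. The submitters' processing notes name GenomeStudio 2011.1. Groups were taken from the labels of genotype and tissue, and the mouse identifiers of the labels showed that every replicate of a group was a separate mouse. Brain and muscle came from the same 7 mice, so that 15 mice gave the 22 arrays.

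The authors deposited a non-normalized table with 1 linear intensity and 1 detection p-value per probe and array. Per the file headers these intensities were not normalized, and 0 of them lay below 0. The deposited detection p-value moved in steps of 0.00125 and was read as the rank of a probe among the negative controls of its array. A table of the authors' processed values of the same arrays held 1 value per probe, with array medians between 15.0 and 15.1 and about 4200 values below 0 per array. Its values ranked the probes of each array exactly as the non-normalized table did, so the direction was that of the raw intensity. Per array they correlated over probes with the raw intensity at 0.969 to 0.999 and with its log2 at 0.735 to 0.851, so they were read as linear, with another zero and unknown scaling. The method of background subtraction and normalization behind that table is not given in the sources used here, and the table served only as an alternative. No 2 arrays held identical values. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 had none. The entrez identifiers of 23962 probes were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Probes without a symbol were tested but not named. No genome was used, and the position of the Sgms1 probe relative to the mutation is not given in the sources used here.

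Intensities of each tissue were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp with negative controls inferred from the detection p-values, offset 16, log2). A probe was kept in a tissue when its detection p was under 0.05 on at least 3 arrays of that tissue. Mutant and wild type were compared per tissue with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment at 5% over the probes kept. All adjusted p-values of single probes in the text come from limma. Where a probe was detected on no array of a group, its fold was computed against the lowest detected signal of each array and is written as "at least". The exact permutation tests beside them were two-sided. A tissue with 3 wild-type and 4 mutant arrays, or with 4 of each, cannot give an exact p below 0.0286. Differences of the genotype effect between tissues were tested in limma on values normalized together, brain minus muscle within the mouse and the others as an interaction term.

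Gene lists were written from textbook knowledge of the tissues and of sphingolipid metabolism. Of 44 lists, 19 served every tissue and the others 1 tissue. They were tested with camera of limma at a preset inter-gene correlation of 0.01, on the probe of highest mean per gene, for lists with at least 5 measured genes, and adjusted over the lists of a tissue. Genes named in the text followed a rule. It took Sgms1, Sgms2 and Samd8 always. It took the 12 largest rises and the 12 largest falls past the threshold without overlap between genotypes. Where these gave fewer than 10 genes, it added genes of smallest p, said not to pass, until 10 were named. It took up to 4 members of smallest p per reported list and the 5 probes of smallest p per difference between tissues. Features named outside the rule are said to be chosen after their values were seen. The grouping, tests, lists, naming rule and the alternatives listed next were fixed before the data were examined.

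These alternatives were quantile normalization without background correction, an offset of 50, median scaling in place of quantile normalization, all 22 arrays normalized together, the authors' processed values (log2 after adding 16, with values below 0 raised to 0), no detection filter, detection p under 0.01 on every array of a genotype, 1 fit over all 22 arrays, eBayes with trend and robust options, array weights, the replicate number as a block, 1 probe per gene, a fold of at least 1.5, an estimated inter-gene correlation, the rotation test fry, and leaving out each replicate. A block on the slide was planned but not run, since the tables used here give no slide. Chosen after seeing the data were fits without both brain libraries whose Sgms1 level went against their label, with the labels of these 2 libraries exchanged, without the 2 wild-type muscle libraries that had Ucp1 signal, and with the Adipoq level of each muscle library as a covariate. Without the muscle libraries with Ucp1 signal 1 wild-type library was left against 4 mutants, which the fit assumes to vary like the mutants.

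The fits were tested on simulated data in which 100 probes per comparison were changed 2-fold and 100 were changed 4-fold. Of the probes changed 2-fold, 88% were recovered in testis, 88% in brain and 87% in muscle, and of those changed 4-fold 98%, 98% and 99%. Among unchanged probes 6 were called in testis, 13 in brain and 7 in muscle. The simulated noise was normal and independent between probes, on normalized values with correct labels. It held no differences in tissue content between libraries. The many changed probes of each fit also loosened the Benjamini-Hochberg cutoff, which is stricter where few probes change. For these reasons the measured data may give lower recovery, and a lone 2-fold change may be missed. For differences between tissues, 71% of 2-fold changes were recovered for brain minus muscle, 61% for testis minus brain and 67% for testis minus muscle. Detected probes per array numbered from 10560 to 12108 in testis, from 14676 to 15299 in brain and from 10652 to 11466 in muscle. The number of arrays per group limits the precision. The median standard error of a log2 difference was 0.15 in testis, 0.12 in brain and 0.13 in muscle.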

Results

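Gene expression was measured in testis of 4 wild-type and 4 Sgms1 mutant mice aged 27 weeks, and in brain and muscle of 3 wild-type and 4 Sgms1 mutant mice aged 17 weeks. The series compared mutant with wild-type mice and speaks of male mice. Median intensity per array ran from 93.7 to 107 in testis, from 112 to 143 in brain and from 133 to 143 in muscle. The dimmest array, testis wild type 2, had 95% of its probes below an intensity of 250, and the brightest testis array had 95% below 553. After the detection filter 12487 probes of 8977 genes were compared in testis, 15264 probes of 10396 genes in brain and 11391 probes of 8101 genes in muscle.

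The mutated gene was examined first. Sgms1 was measured by 1 probe in all 3 tissues. In muscle its log2 level was 7.98 ± 0.19 (SD, n = 3) in wild type and 7.28 ± 0.16 (SD, n = 4) in mutants, a difference of -0.70 (SE 0.13), or 1.63-fold lower. All 4 mutant libraries lay below every wild-type library (exact permutation p = 0.0286, the smallest the design allows). The muscle difference missed the threshold over all probes (adjusted p = 0.0871) and passed it with median scaling (where the median of all muscle differences was -0.05) or with the trend and robust options of limma. In testis the level was 6.05 ± 0.47 (SD, n = 4) in wild type and 5.43 ± 0.50 (SD, n = 4) in mutants, a difference of -0.62 (SE 0.26, adjusted p = 0.833, exact permutation p = 0.143). In brain the difference was -0.78 (SE 0.45, adjusted p = 0.999, exact permutation p = 0.229), and 2 libraries went against their labels. The brain library labelled wild type 3 had a level of 6.62, beside 8.31 and 8.05 in the other libraries labelled wild type. The brain library labelled mutant 2 had 8.12, beside 6.57, 6.29 and 6.54 in the other libraries labelled mutant. Without both of these libraries, a setting chosen after seeing the data, the brain difference was -1.71 (SE 0.15, adjusted p = 0.00313), and with their labels exchanged, also chosen after seeing Sgms1, it was -1.65 (SE 0.11, adjusted p = 1.87e-04, the lowest of 1.87e-04 to 1.0 over the alternatives for brain Sgms1). Both settings were picked by the Sgms1 level itself, so these 2 p-values add no support of their own. Without the library labelled wild type 1 the brain difference was -0.45. The genotype of these brain libraries is in doubt, and every direction and count given for brain carries that doubt. The probe was detected in all mutant libraries of every tissue, and whether the probe lies within the mutated part of the gene is not given in the sources used here.

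**Figure D1:**
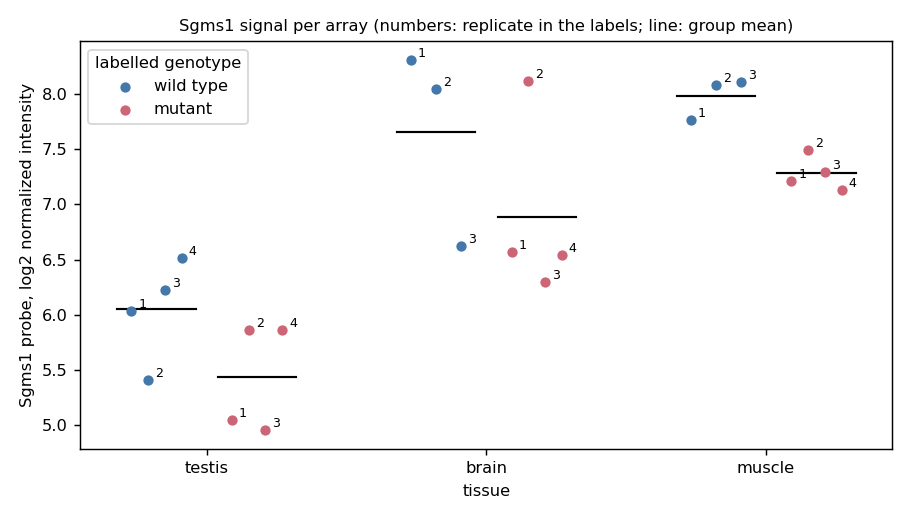
Log2 normalized intensity of the Sgms1 probe on each of the 22 arrays by tissue and labelled genotype, with replicate numbers beside the points and a line at each group mean. Mutant muscle libraries lie below all wild-type ones, and in brain the library labelled wild type 3 (6.62) and the library labelled mutant 2 (8.12) lie with the opposite genotype.

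The other sphingomyelin synthase, Sgms2, and the related ceramide phosphoethanolamine synthase Samd8 did not pass the test in limma in any tissue where they were tested. Samd8 differed by 0.04 (SE 0.25) in testis, 0.03 (SE 0.12) in brain and 0.06 (SE 0.11) in muscle on the log2 scale, and its direction changed with single libraries, to -0.28 in testis without wild type 2. Sgms2 differed by -0.15 (SE 0.14) in testis (-0.07 without wild type 4 and -0.04 without mutant 3) and by 0.18 (SE 0.12) in brain (0.09 without wild type 2 and 0.10 without mutant 2, by label), where it was detected in 2 of 3 libraries labelled wild type and 3 of 4 labelled mutant. It was detected in 0 muscle libraries. The list of sphingomyelin synthesis and hydrolysis genes did not pass in testis (adjusted p = 0.427), brain (adjusted p = 0.953) or muscle (adjusted p = 0.702).

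In muscle, the largest fall was that of Lep, which encodes the fat cell hormone leptin, from 8.54 ± 0.49 (SD, n = 3) to 5.77 ± 0.31 (SD, n = 4), 6.85-fold lower. Sncg, encoding gamma-synuclein, was 5.29-fold lower, Angptl4, a secreted inhibitor of lipoprotein lipase, 3.56-fold lower, and the retinol-binding protein gene Rbp7 2.96-fold lower. Dbp, a transcription factor under direct control of the circadian clock, was 2.06-fold higher, and Bhlhe40, a repressor in the clock, 1.79-fold higher. Map4, encoding a microtubule-associated protein, rose 2.23-fold.

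Among 11391 muscle probes, 12 passed the 5% threshold in limma, 6 higher and 6 lower in the mutants, and 10 of them had a gene symbol. This balance depended on the processing, with 18.9% of calls higher with median scaling and 28.6% without background correction. At an unadjusted p under 0.05 there were 1043 probes, where 570 would be expected by chance. On the log2 scale the differences were -2.78 for Lep (SE 0.23, adjusted p = 0.00108), -1.56 for Rbp7 (SE 0.13, adjusted p = 0.00108), -1.83 for Angptl4 (SE 0.21, adjusted p = 0.00691) and -2.40 for Sncg (SE 0.32, adjusted p = 0.0186). Hp, encoding the haemoglobin-binding plasma protein haptoglobin, differed by -1.42 (SE 0.17, adjusted p = 0.0120). Cdsn, encoding the skin adhesion protein corneodesmosin, differed by -1.70 (SE 0.25, adjusted p = 0.0407) and was detected in 3 of 3 wild-type and 1 of 4 mutant libraries. The rises were 1.15 for Map4 (SE 0.10, adjusted p = 0.00162), 1.04 for Dbp (SE 0.13, adjusted p = 0.0120) and 0.84 for Bhlhe40 (SE 0.13, adjusted p = 0.0486). Taf6, encoding a subunit of the general transcription factor TFIID, rose by 1.39 (SE 0.14, adjusted p = 0.00308) on a probe detected in 2 of 3 wild-type libraries, while its second probe differed by 0.02 (SE 0.12). For Hp and Sncg, further detected probes gave differences of -1.49 and -1.81 for Hp and -1.59 for Sncg, with adjusted p of 0.0670, 0.0688 and 0.0512. The second probes of Map4 and Rbp7 were detected on 0 muscle arrays, and that of Cdsn in 1 of 3 wild-type and 0 of 4 mutant libraries, so that these gave no support. On the probe of each of the 10 genes that passed, all 4 mutants lay beyond all 3 wild-type mice (exact permutation p = 0.0286). The naming rule asked for this separation, so it adds no support of its own. Over all muscle probes, 1011 had groups that did not overlap, 8.88% against 5.71% by chance.

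Several of these calls depended on single libraries. The number of probes past the threshold was 21 without wild type 1, 22 without wild type 3 and 19 without mutant 3. Bhlhe40 missed the threshold without any 1 library other than mutant 1, with adjusted p of 0.0960 without wild type 1, 0.0520 without wild type 2, 0.129 without wild type 3, 0.180 without mutant 2, 0.0704 without mutant 3 and 0.147 without mutant 4. Without wild type 2, Sncg (adjusted p = 0.0658), Cdsn (0.116), Hp (0.0608) and Dbp (0.0592) also missed it. Without mutant 2, Sncg (0.112), Cdsn (0.180) and Hp (0.0676) missed it, without mutant 1 Sncg (0.0556) and Cdsn (0.0992), and without mutant 4 Cdsn (0.120). Lep, Rbp7, Angptl4, Map4 and Taf6 passed in every fit that left out 1 library. Without background correction the differences were smaller for Lep (-1.53), Rbp7 (-0.94) and Map4 (0.41), and those of Taf6 (0.40), Sncg (-1.57), Hp (-0.71), Cdsn (-0.52) and Bhlhe40 (0.71) also missed the threshold. With the authors' processed values Lep, Rbp7 and Map4 alone of the 10 genes passed (adjusted p of 0.0664 for Taf6 and 0.127 for Angptl4 and Dbp), and without the detection filter these 3 and Taf6 (0.128 for Angptl4 and 0.0771 for Dbp). Bhlhe40 (0.0989), Sncg (0.0741), Cdsn (0.0989) and Hp (0.0576) missed the threshold with all arrays normalized together. Sncg also missed it with the trend and robust options (0.135), Bhlhe40 (0.0537) and Hp (0.0565) with the replicate block, Bhlhe40 and Cdsn with 1 probe per gene (0.0554 each) and Cdsn with an offset of 50 (0.0653). The fit with 1 probe per gene left out the called probes of Taf6 and Hp, since another probe of each gene had the higher mean. Values given here for these genes do not cover that fit. Over all alternatives tried, those with the Adipoq covariate included, the adjusted p ran from 1.37e-07 to 0.410 for Lep, from 1.72e-07 to 0.398 for Rbp7, from 3.86e-05 to 0.398 for Map4, from 6.80e-04 to 0.398 for Taf6, from 1.19e-05 to 0.956 for Angptl4 and from 3.39e-04 to 0.746 for Dbp, and it reached 0.999 for Bhlhe40, Cdsn, Hp and Sncg.

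**Figure D2:**
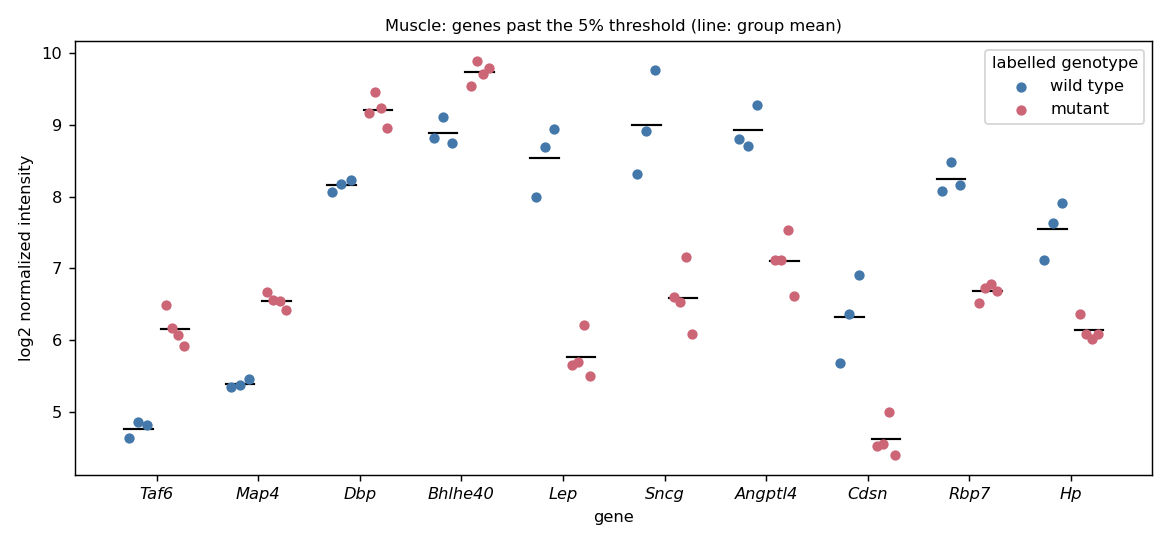
Log2 normalized intensity in muscle of the 10 named genes past the 5% threshold, with 1 point per library, colours for labelled genotype and a line at each group mean. The 3 wild-type and 4 mutant libraries do not overlap for any of the 10 genes.

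The fixed list of adipocyte genes was lower in mutant muscle, with a mean log2 difference of -1.19 over 7 measured genes (adjusted p = 2.49e-08, and adjusted p = 0.293 with an estimated correlation). All 7 were lower, 1 of them (Lep) fell over all probes and 5 fell when adjusted over the list alone. Adipoq, which encodes the fat cell hormone adiponectin, differed by -1.78 (SE 0.36), the lipid droplet gene Cidec by -2.12 (SE 0.47) and the lipid droplet coat gene Plin1 by -0.59 (SE 0.20, and -0.33 without wild type 3). Adipoq levels were 10.41, 10.50 and 11.46 in wild-type mice and 9.45, 8.54, 9.77 and 8.29 in mutants. Wild types 1 and 3 also had signal for Ucp1, the uncoupling protein of brown fat, at 7.26 and 7.72, while the other 5 muscle libraries lay between 4.22 and 4.40 and were not detected. Ucp1 was chosen after its values were seen. With the Adipoq level as a covariate, also chosen after seeing the data, the Lep difference was -2.0 (SE 0.33, adjusted p = 0.410) and 0 probes passed the threshold in limma, with 443 at an unadjusted p under 0.05. The adipocyte list, which holds Adipoq itself, had a mean of -0.14 there (adjusted p = 0.873). The standard errors of the called genes rose in that fit. The differences of Sncg (-1.08, SE 0.35), Angptl4 (-1.01, SE 0.25), Cdsn (-0.85, SE 0.36), Hp (-1.05, SE 0.31) and Bhlhe40 (0.57, SE 0.23) were smaller there, while those of Rbp7 (-1.64, SE 0.25), Map4 (1.32, SE 0.19), Dbp (1.15, SE 0.25) and Taf6 (1.64, SE 0.26) were not.

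The circadian clock list was higher in mutant muscle, by 0.33 on average over 12 measured genes, of which 9 were higher (adjusted p = 5.97e-04, and adjusted p = 0.189 with an estimated correlation). Dbp and Bhlhe40 rose over all probes, and 5 genes rose when adjusted over the list alone. Nr1d1, encoding the clock repressor REV-ERB alpha, differed by 0.52 (SE 0.13) and the period gene Per2 by 0.56 (SE 0.17). By the rotation test fry this list moved on balance in 1 direction (adjusted p = 0.00577). With Adipoq as a covariate its mean was 0.40 (adjusted p = 0.00132, and adjusted p = 0.315 with an estimated correlation), and fry did not pass (adjusted p = 0.0869). The time of day at which tissue was taken is not given in the sources used here.

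Lists of lipid metabolism were lower as well. Of 17 measured genes of fatty acid oxidation 14 were lower, by -0.26 on average (adjusted p = 0.00140, and adjusted p = 0.293 with an estimated correlation). Angptl4 fell over all probes, and 3 genes fell when adjusted over the list alone. Angptl4 acts on lipoprotein lipase and not on oxidation itself. Pdk4, a kinase that shuts off pyruvate dehydrogenase, differed by -0.45 (SE 0.11) and the mitochondrial carrier gene Ucp3 by -0.79 (SE 0.19). Of 20 measured genes of cholesterol and fatty acid synthesis 16 were lower, by -0.32 on average (adjusted p = 0.00701, and adjusted p = 0.293 with an estimated correlation). Of these 0 fell over all probes and 4 fell when adjusted over the list alone. The desaturase gene Scd1 differed by -2.22 (SE 0.42), the elongase gene Elovl6 by -0.99 (SE 0.25), Acly by -0.99 (SE 0.26) and Acaca by -1.10 (SE 0.34). Adipoq was 3.43-fold lower in the same mutant libraries. With Adipoq as a covariate the synthesis list had a mean of -0.0144 (adjusted p = 0.873) and the oxidation list -0.16 (adjusted p = 0.243). Without the libraries of wild types 1 and 3, which leaves 1 wild-type library, the synthesis list had a mean of -0.18 (adjusted p = 0.120), with Elovl6 at -0.25, Acly at -0.41 and Acaca at -0.24.

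Interferon response genes were lower by -0.19 on average over 16 measured genes, 13 of them lower (adjusted p = 0.0121, and adjusted p = 0.788 with an estimated correlation). Extracellular matrix genes were lower by -0.15 over 18 measured genes, 13 of them lower (adjusted p = 0.0198, and adjusted p = 0.788 with an estimated correlation). In both lists 0 genes fell over all probes. Adjusted over the list alone, 1 interferon gene and 2 matrix genes fell. Ifi27l2a differed by -1.19 (SE 0.26), the collagen gene Col4a2 by -0.41 (SE 0.11) and the matrix glycoprotein gene Sparc by -0.58 (SE 0.16). The interferon list missed the threshold without wild type 1 (adjusted p = 0.0998), wild type 2 (0.132) or mutant 4 (0.0938), and the matrix list without wild type 2 (0.104), wild type 3 (mean -0.0876, adjusted p = 0.276), mutant 2 (mean -0.0995, adjusted p = 0.269) or mutant 4 (0.110), while its mean was -0.24 without wild type 1 or mutant 1. With Adipoq as a covariate the matrix list turned to a mean of 0.19 (adjusted p = 0.0777) and the interferon list had a mean of -0.03 (adjusted p = 0.780). Without background correction the means were smaller for the adipocyte (-0.78), clock (0.22) and interferon lists (-0.10). Of 24 lists tested in muscle, 6 passed with the preset correlation, 0 with an estimated correlation and 1 with fry. At an unadjusted p under 0.05 these numbers were 7, 4 and 5. Over all alternatives the adjusted p ran from 4.76e-12 to 0.873 for adipocyte genes, from 4.21e-06 to 0.189 for clock genes, from 1.08e-04 to 0.293 for oxidation, from 4.86e-04 to 0.873 for synthesis, from 7.16e-04 to 0.788 for interferon and from 2.85e-04 to 0.788 for matrix genes.

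**Figure D3:**
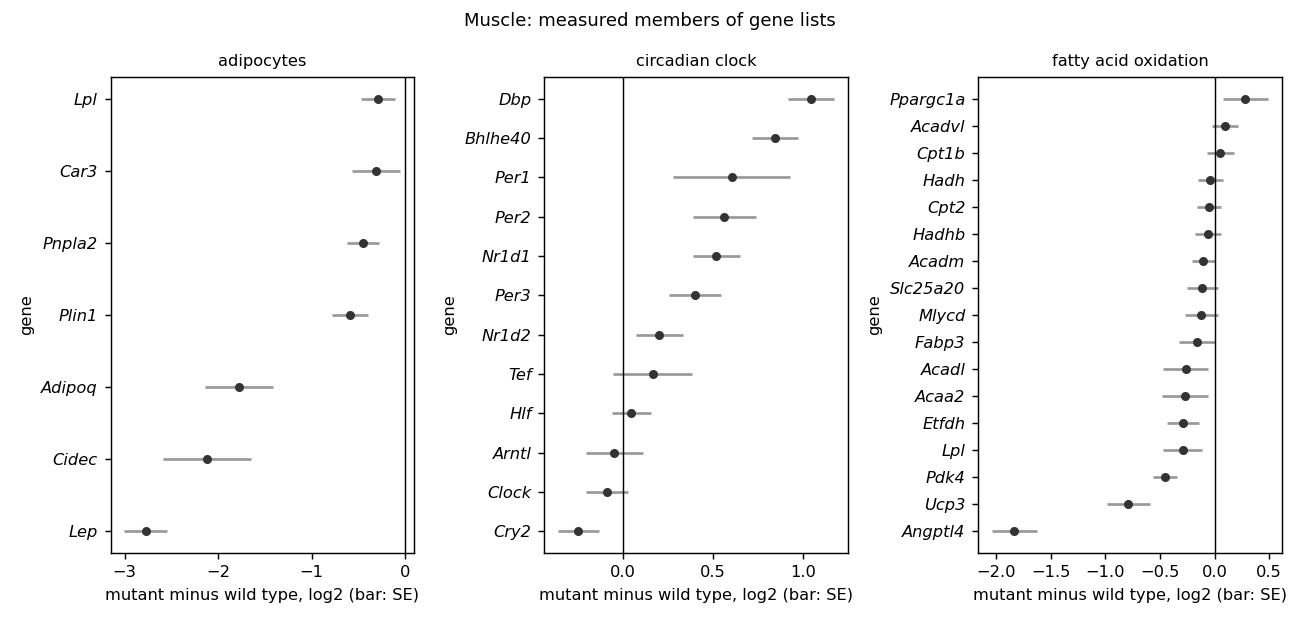
Mutant minus wild-type log2 difference in muscle for each measured gene of the adipocyte, circadian clock and fatty acid oxidation lists, with bars of 1 SE. All 7 adipocyte genes and 14 of 17 oxidation genes lie below 0, and 9 of 12 clock genes lie above it.

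Other fixed muscle lists did not pass. Of 11 genes of the slow fibre program 8 were higher, by 0.64 on average (adjusted p = 0.222). The slow troponin gene Tnnt1 was at 6.22, 6.67 and 6.63 in wild-type mice and at 10.11, 10.80, 6.86 and 8.29 in mutants. Its difference was 2.51 (SE 0.75, adjusted p = 0.305), and that of the slow troponin C gene Tnnc1 was 1.35 (SE 0.79, adjusted p = 0.678), with 0.82 without mutant 2 and 2.08 without mutant 3. Tnnc1 (10.02 and 10.33) and Atp2a2 (10.91 and 11.10) were also highest in mutants 1 and 2, while Pln was not (4.48 and 4.76). Myh7, named after its values were seen, was detected in these 2 muscle libraries only. The rise was thus uneven between mutant libraries, and whether the pieces differed in fibre content was not tested. The lists of the fast fibre program (adjusted p = 0.663), oxidative phosphorylation (0.702), immune cells (0.999) and ceramide and glycosphingolipid metabolism (0.517) did not pass. In the last of these Asah2, encoding a neutral ceramidase, differed by 0.41 (SE 0.11). Asah2 is also on the list of neighbours of Sgms1, so its difference cannot be credited to ceramide metabolism alone. The neighbours of Sgms1 on chromosome 19, by the order of genes in assembly GRCm38.p6, did not pass either (adjusted p = 0.962). Camera asks for a shift of a list in 1 direction, and its members went both ways. While Asah2 was higher, Gldc was at 4.75, 5.12 and 5.21 in wild-type mice and at 4.35, 4.51, 4.29 and 4.32 in mutants. Neither passed over all probes. The list result therefore does not show that the neighbours kept their levels.

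In brain 0 of 15264 probes passed the threshold in limma, and 586 had an unadjusted p under 0.05 where 763 would be expected by chance. The groups did not overlap for 4.44% of probes, against 5.71% by chance. The genes of smallest p did not pass. Among them Mcm6, a subunit of the replicative DNA helicase, was higher by 0.79 (SE 0.16) and Uhrf1, needed to maintain DNA methylation, by 0.43 (SE 0.09) in libraries labelled mutant. The other genes of this rank were Prl2c4 (-0.58, detected in 2 of 4 libraries labelled mutant), Rnf207 (-0.44), Zfp24 (-0.45), Lrpprc (-0.45), Prss8 (-0.55, detected in 1 of 4), Cmc2 (0.44) and Frzb (-0.40), and Spire1 by a probe detected in 0 of 4 and at least 1.25-fold lower there. For the probe of each of these the adjusted p was 0.999 and the exact permutation p was 0.0286. The latter adds no support of its own, since the genes were picked by smallest p. Other detected probes of some genes differed less or went the other way, with 0.32 and 0.37 for Mcm6, 0.13 and 0.0013 for Lrpprc, 0.17 for Prss8, and -0.20, -0.21 and 0.17 for Spire1. The genotype doubt described for Sgms1 covers every direction and count in this paragraph, since 2 libraries may be in the wrong group. With the labels of these 2 exchanged, chosen after seeing Sgms1, 5 probes passed in limma and 1286 had an unadjusted p under 0.05. The counts by label therefore do not show that brain expression was unchanged in the mutants.

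Of 24 lists 0 passed in brain by camera, with an estimated correlation or by fry, and the numbers at an unadjusted p under 0.05 were 2, 0 and 0. The smallest adjusted p was 0.265, for interferon genes, where the antiviral gene Rsad2 differed by -0.38 (SE 0.12). In sphingolipid lists the neutral sphingomyelinase gene Smpd2 differed by -0.32 (SE 0.09), the ceramide synthase gene Cers4 by -0.27 (SE 0.10), Sptlc2, a subunit of serine palmitoyltransferase, by -0.34 (SE 0.13), and the GM3 synthase gene St3gal5 by 0.30 (SE 0.11), with 0 members past the threshold over all probes and 0 when adjusted over the list alone. The ceramide list did not pass (adjusted p = 0.892). Pituitary hormone genes stood apart in 2 libraries. Growth hormone (Gh) was at 14.02 and 12.15 in the libraries labelled wild type 2 and wild type 3 and between 4.29 and 5.78 in the other 5. Prolactin (Prl) was at 13.48 and 11.13 there and between 4.51 and 5.05 elsewhere. The list of hypothalamic and pituitary peptides had a mean difference of -1.18 and a median of -0.05 over 12 measured genes (adjusted p = 0.340).

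Calls in brain changed with single libraries. Without the library labelled wild type 1 there were 2 probes past the threshold. These were the pituitary genes Prl (-7.40) and Gh (-7.83), with a limma adjusted p of 3.81e-04 each. Both were high only in the libraries labelled wild type 2 and wild type 3. Without the library labelled wild type 3 there were 5 probes past the threshold. The number of lists past it was 1 without wild type 1, 2 without wild type 2, 1 without wild type 3 and 2 without mutant 2, by label. Without both libraries whose Sgms1 level went against the label there were 6 probes, 4 higher and 2 lower in libraries labelled mutant, with 868 at an unadjusted p under 0.05. Of these, named after their values were seen, Actl6b, encoding a subunit of the neuronal chromatin remodelling complex, differed by 3.02 (SE 0.27, adjusted p = 0.00313), Pdrg1 by 1.09 (SE 0.13), Cops8 by 0.99 (SE 0.13) and Bfar by -1.17 (SE 0.13). The fifth was Sgms1 itself, by which the 2 libraries were picked in this setting and the next, and the last a probe without a symbol. In that setting the immune cell list (adjusted p = 1.01e-05, and adjusted p = 0.613 with an estimated correlation) and the microglia list (adjusted p = 0.00193, and adjusted p = 0.613 with an estimated correlation) were higher in libraries labelled mutant. With the labels of the 2 libraries exchanged there were 5 probes, with 1286 at an unadjusted p under 0.05. Named after their values were seen, these were Sgms1, Actl6b (2.86, SE 0.22), Taf6 (1.51, SE 0.21, on the probe that rose in muscle), the pyruvate kinase gene Pkm (0.68, SE 0.09) and a probe without a symbol. The immune cell list (adjusted p = 9.01e-10, and adjusted p = 0.251 with an estimated correlation) and the microglia list (adjusted p = 5.26e-06, and adjusted p = 0.251 with an estimated correlation) passed in that setting too.

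In testis 0 of 12487 probes passed the threshold in limma, and 692 had an unadjusted p under 0.05 where 624 would be expected by chance. The groups did not overlap for 3.42% of probes, against 2.86% by chance. The genes of smallest p did not pass. Ccdc57 differed by -0.75 (SE 0.11, adjusted p = 0.212), Olfr303 by -0.89 (SE 0.15, adjusted p = 0.395) and Ccdc27 by -0.77 (SE 0.14, adjusted p = 0.448), and the p38 alpha kinase gene Mapk14 by 0.55 (SE 0.12, adjusted p = 0.736). The others of this rank were BC048671 (-0.70), Gm1673 (-0.63), Gatad1 (-0.60), Rusc2 (-0.54), the mitochondrial ribosomal gene Mrpl27 (-0.56) and Tbc1d19 (-0.55), each at an adjusted p of 0.736. On the probe of each of these 10 genes all 4 mutants lay beyond all 4 wild-type mice (exact permutation p = 0.0286). Since the genes were picked by smallest p, this separation adds no support of its own. The genotypes overlapped on every other detected probe of the same genes, with differences of 0.02 and 0.0037 for Ccdc27, 0.12 and 0.11 for Gatad1, -0.17 for Rusc2 and -0.45 for Gm1673. Of these Ccdc57 passed without the detection filter (adjusted p = 0.0223) and in 1 fit over all 22 arrays, and over the alternatives for testis Ccdc57 the adjusted p ran from 0.00314 to 0.995. With median scaling the median of all testis differences was 0.12, so that single differences of that setting are relative to it.

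Genes of elongating and condensed spermatids were lower in mutant testis by -0.18 on average. Of 20 measured genes 16 were lower (adjusted p = 0.0212, and adjusted p = 0.754 with an estimated correlation). Of these 0 fell over all probes and 1, the protamine gene Prm3, fell when adjusted over the list alone. Prm3 differed by -1.08 (SE 0.24, adjusted p = 0.736), and all 4 mutants lay below all 4 wild-type mice. The transition protein gene Tnp2 differed by -0.57 (SE 0.23, and -0.34 without mutant 1) and the protamine gene Prm1 by -0.41 (SE 0.17, and -0.25 without wild type 2). The list missed the threshold without wild type 3 (adjusted p = 0.119), wild type 4 (0.124), mutant 1 (0.139) or mutant 3 (mean -0.11, adjusted p = 0.290), with all arrays normalized together (0.0508) and without the detection filter (0.0519), and over all alternatives its mean ran from -0.26 to -0.0561 (the latter with median scaling) and its adjusted p from 2.20e-04 to 0.754. The number of lists past the threshold was 3 without wild type 1 and 3 without wild type 2.

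Of 27 lists in testis, 1 passed with the preset correlation, 0 with an estimated correlation and 0 by fry, and the numbers at an unadjusted p under 0.05 were 4, 0 and 2. Spermatogonia (adjusted p = 0.687), meiotic spermatocytes (0.692), round spermatids (0.692), Sertoli cells (0.359) and Leydig cells (0.345) did not pass. Nor did the ceramide and glycosphingolipid list (adjusted p = 0.14), in which 19 of 25 genes were higher and 0 passed over all probes or when adjusted over the list alone. The glucosylceramide synthase gene Ugcg differed by 0.40 (SE 0.15), the sphingosine-1-phosphate phosphatase gene Sgpp1 by 0.42 (SE 0.17) and the ceramide synthase gene Cers2 by 0.31 (SE 0.13). In the apoptosis and p53 list 11 of 16 genes were higher (adjusted p = 0.14), with Sesn2 at 0.43 (SE 0.17) and Bbc3 at 0.36 (SE 0.14). In the Leydig cell list Ptgds differed by -0.65 (SE 0.26, and -0.33 without wild type 1). Epididymal genes had signal in 7 testis libraries, of both genotypes, and were low in 1. Spint4 was at 4.51 and Adam7 at 5.10 in wild type 4, while the other 7 testis libraries lay between 9.27 and 10.21 for Spint4 and between 9.89 and 11.07 for Adam7. The epididymis list did not pass (adjusted p = 0.290).

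**Figure D4:**
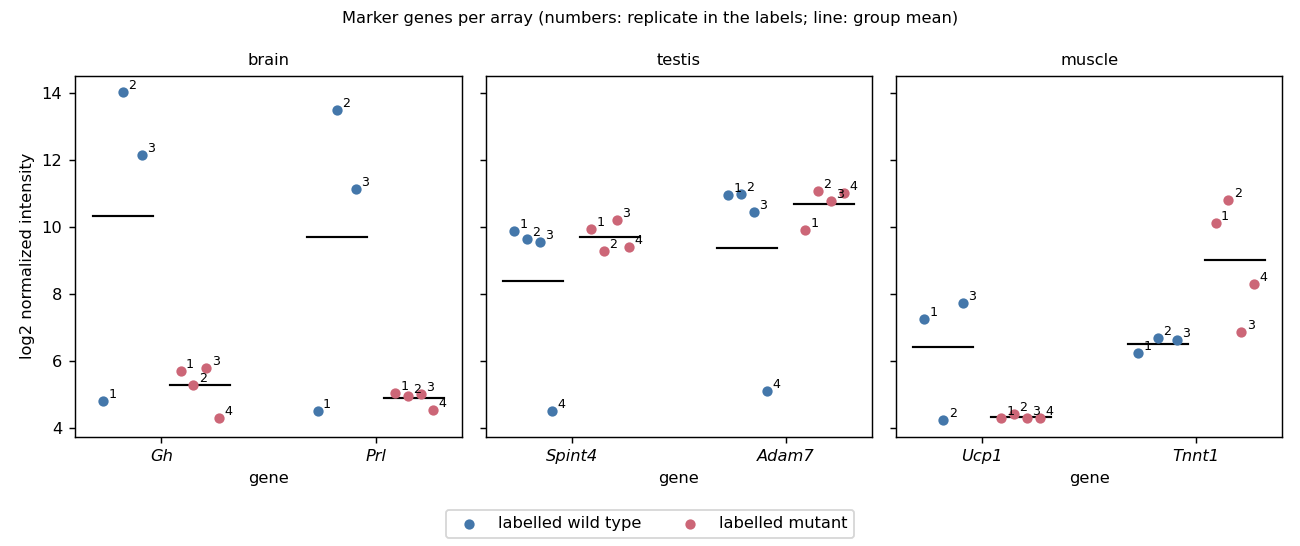
Log2 normalized intensity per library of pituitary genes (Gh, Prl) in brain, epididymal genes (Spint4, Adam7) in testis, and Ucp1 and Tnnt1 in muscle, by labelled genotype with replicate numbers and a line at each group mean. Gh and Prl are high in the libraries labelled wild type 2 and 3, both epididymal genes are low in wild type 4, and Ucp1 is detected in wild types 1 and 3.

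Whether the genotype effect differed between tissues was tested directly. Brain minus muscle, within the same 7 mice, differed for 4 of 10582 probes, all higher, with adjusted p of 0.0473 each and 784 probes at an unadjusted p under 0.05. These were Sncg (2.19, SE 0.27), Angptl4 (1.74, SE 0.23), Hp (1.48, SE 0.19) and Rbp7 (1.43, SE 0.16), and in brain by itself their differences lay between -0.05 and 0.22. Map4 differed by -1.10 (SE 0.17, adjusted p = 0.104). The number past the threshold was 2 without wild type 1, 1 without wild type 3 and 0 without wild type 2, mutant 1, mutant 2 or mutant 4, and it was 1 (Rab6b, -2.22, SE 0.21, named after its value was seen) without both mice whose brain library was in doubt. With the 2 brain libraries in doubt exchanged it was 14, among them the 4 genes named and Map4 (-1.35, SE 0.14). With the authors' processed values it was 0. Genes lower in mutant muscle here and in the next comparison were lower in libraries that also had less Adipoq (-1.78). Because both genotypes of brain enter this test, the doubt about these labels covers it.

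Testis minus muscle differed for 7 of 9187 probes, 5 higher and 2 lower, with 636 at an unadjusted p under 0.05. Lep differed by 2.56 (SE 0.37, adjusted p = 0.00651), Sncg by 2.23 (SE 0.34, adjusted p = 0.00720), Angptl4 by 1.93 (SE 0.26, adjusted p = 0.00537) and Map4 by -1.20 (SE 0.18, adjusted p = 0.00695). Mmd differed by 1.79 (SE 0.27, adjusted p = 0.00695), from 0.50 (SE 0.14) in testis and -1.24 (SE 0.21) in muscle. Cdsn, named after its value was seen, differed by 1.88 (SE 0.32, adjusted p = 0.0159). With the authors' processed values 0 probes passed, and with each tissue normalized by itself 16 passed. Testis minus brain differed for 0 of 10487 probes in limma, with 449 at an unadjusted p under 0.05, and the 5 of smallest p were Dsn1 (0.92), Mrpl27 (-0.82), Arhgef6 (0.79), Ccdc57 (-0.73) and Gm1673 (-0.85). Testis came from mice aged 27 weeks and the other tissues from mice aged 17 weeks, so age and tissue cannot be told apart in comparisons with testis.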

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

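All tests of an explanation in this part, on the brain labels, the fat cell genes and the clock genes, were chosen after the result was seen, while the counts over other splits of the differences between tissues were planned.

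The brain library labelled mutant 2 had an Sgms1 level of 8.12, far from 6.57, the nearest of the other 3 libraries labelled mutant, and the library labelled wild type 3 was low at 6.62. Noise of the single Sgms1 probe is argued against, since over the 200 probes that varied most between mice in both tissues, without Sgms1, these libraries correlated with the muscle of their own mouse at most at 0.0565, below 0.415, the lowest of the other 5 brain libraries, and over 500 probes at 0.146 and 0.0161, below 0.193 (correlations across probes, which are not independent). An exchange of the mice or of the muscle libraries is argued against as well, since the lowest wild-type muscle level of Sgms1 lay 0.268 above the highest mutant one. An exchange of the 2 brain libraries with each other is a candidate explanation: the library labelled wild type 3 matched the muscle of mutant 2 best (0.506) and the library labelled mutant 2 that of wild type 3 (0.584), each above its own mouse by at least 0.450, and over 500 probes, where the best matches were the same, less clearly (0.309 and 0.277). Over 100 probes the library labelled wild type 3 matched the muscle of mutant 2 at 0.684 and its own mouse at -0.0411. The library labelled mutant 2 matched the muscle of wild type 3 at 0.738 and its own mouse at -0.0438. The Y-linked gene Eif2s3y, picked after its values were seen, was undetected in the brain library labelled mutant 2 (4.22) and in muscle wild type 3 (4.26). It lay between 7.44 and 8.52 in the other 12 libraries of both tissues. The Y-linked genes Kdm5d (6.22 and 5.27) and Uty (5.43 and 4.89) were detected in these 2 libraries and Xist was not. The pair without Eif2s3y is one that the correlations matched, so this gene goes with an exchange of the brain libraries too.

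The adipocyte list was lower in mutant muscle (adjusted p = 2.49e-08, and adjusted p = 0.293 with an estimated correlation), with Lep past the threshold over all probes and the other 6 measured genes not. Less white fat in the mutant muscle pieces may account for the lower values: in a further list of 20 white fat genes, at least 3 of which (Gpd1, Plin4 and Dgat2) muscle fibres also express and 0 of which are in another list, 16 of 16 measured genes were lower, 0 of them past the threshold by themselves, with a median of -0.77 (camera p = 3.09e-15, and p = 0.0343 with an estimated correlation), and over the 14 whose muscle values had not been looked at before it was -0.72. Of its probes with the highest signal Plin4 was at 11.38 in wild type and 10.73 in mutants, Cyp2e1 at 10.30 and 10.05, and Aoc3 at 10.13 and 8.31, while the Fabp4 probe was detected on 0 of the 22 arrays of any tissue and tells nothing. Brown fat in wild types 1 and 3 as the whole cause stays open, since the list was lower without them (adjusted p = 3.54e-05) but 1 wild-type library was left, and brown fat expresses many of these genes too. Open remain also whether a lower amount of the same fat explains all of the Lep fall (Lep minus Adipoq differed by -1.0, exact permutation p = 0.0571) and whether the mutation acts beyond the amount of fat (Lep -2.78 with SE 0.23 before and -2.0 with SE 0.33 after the Adipoq covariate, where a smaller difference with a larger error ended the call), since fat content and genotype cannot be told apart in 7 mice.

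The clock list was higher in mutant muscle (adjusted p = 5.97e-04, and adjusted p = 0.189 with an estimated correlation), with Dbp and Bhlhe40 past the threshold over all probes. Less fat in the mutant pieces stays open as the cause, since fat content and genotype went together in these mice. With Adipoq as a covariate the list mean did not shrink (0.33 before, 0.40 after). The list passed camera at the preset correlation (adjusted p = 0.00132) but not with an estimated correlation (adjusted p = 0.315) or by fry (adjusted p = 0.0869). Dbp (1.04 with SE 0.13 before, 1.15 with SE 0.25 after) lost its call by a larger error. Bhlhe40 (0.84 with SE 0.13 before, 0.57 with SE 0.23 after) lost it also by a smaller difference. A different time of dissection could shift clock genes in both tissues of a mouse. In brain the clock list did not pass the camera test (adjusted p = 0.764). Camera and a list mean ask for a shift in 1 direction, so neither can exclude a shift in which members go both ways. Without the 2 brain libraries in doubt, Ciart was at 6.60 and 6.95 in those labelled wild type and from 7.16 to 7.52 in those labelled mutant. Per3 (5.16 and 5.17, then 5.52 to 6.14) and Dbp (10.32 and 10.51, then 10.55 to 10.86) were higher too, while Nr1d1 overlapped. These were the 4 clock genes of smallest p in brain. The mean over 11 clock genes, brain minus muscle within the mouse, was lower by -0.34 in mutants (exact permutation p = 0.0286, and 0.100, the smallest possible, without both mice in doubt), which leaves this explanation open because the brain labels are in doubt and few mice remain without them. The mutation itself stays open too (fry adjusted p = 0.00577), since time of dissection and genotype cannot be told apart without recorded times.

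Among 114 groups of 4 libraries tested for a library far from the others, 11 had one, where chance gives about 1 in 20 groups. In testis wild type 4, Spint4 (4.51) and Adam7 (5.10) were far below the other wild-type libraries and Sgms2 (8.33) above them. In testis mutants, Ccdc57 was low in mutant 3 (5.89), BC048671 high in mutant 4 (5.90), Sesn2 high in mutant 3 (5.55), and mutant 2 had 11793 detected probes, fewer than the other 3. In libraries labelled mutant, Prss8 was high in brain mutant 4 (4.62), Sgms2 was high in muscle mutant 4 (4.42, undetected there), and Ucp3 low in muscle mutant 1 (6.94).

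By a test of the difference itself, brain minus muscle differed for 4 probes, Sncg by 2.19, Angptl4 by 1.74, Hp by 1.48 and Rbp7 by 1.43, and the number was 2 without wild type 1, 1 without wild type 3 and 0 without wild type 2, mutant 1, mutant 2 or mutant 4. Of 35 splits of the 7 mice only the real one gave as many, and the highest other gave 1. This is the smallest share that 35 splits allow. It does not exclude chance, since the number fell to 0 without single mice and the brain labels are in doubt. Testis minus muscle differed for 7 probes, among them Lep by 2.56, Sncg by 2.23, Angptl4 by 1.93, Mmd by 1.79 and Map4 by -1.20. Of 100 splits only the real one gave as many, and the highest other gave 2, so such a number was rare among splits. Testis minus brain differed for 0 probes in limma, with 449 at an unadjusted p under 0.05, and since every split gives at least 0 (100 of 100, the highest other with 2), the splits say nothing about chance there. Most of the genes named here are lower in mutant muscle, where less fat in the pieces (Adipoq -1.78) was left open above and was not taken out of these tests.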

How the results depend on the processing

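Fits without the brain libraries in doubt, with their labels exchanged, without muscle wild types 1 and 3 (Ucp1 signal) and with Adipoq as a covariate were chosen after seeing the data. Over all alternatives, values of named genes kept their side of the threshold in 6511 cases (in 80 of them, past it in neither setting, the sign changed), lost the call in 93 and gained one in 41. For gene lists these numbers were 1561 (116 with another camera direction), 32 and 25, with 2 reversals of a call. Of the main counts and Sgms1 values 156 stayed (a count within 1.5 times of the main one, Sgms1 on its side of the threshold), 50 moved and 4 gained a call. Where not said otherwise, the cause was not tested. The 12 muscle probes became 7 without background correction, 37 with median scaling (18.9% higher against 50%), 4 with the authors' processed values, 4 without detection filter, 195 in 1 fit over all 22 arrays (55 higher, 140 lower), 28 with trend and robust options, 22 with array weights, 6 with 1 probe per gene, 4 without wild types 1 and 3 (1 wild-type library left) and 0 with Adipoq (443 at an unadjusted p under 0.05), and leaving out 1 library gave 8 to 22. Of the calls without background correction 28.6% were higher, and of the 8 with joint normalization 62.5%. The number of muscle lists past the threshold went from 6 to 0 with an estimated correlation, to 1 by fry (clock) and to 3 with Adipoq (clock, and oxidative phosphorylation and immune cells, which had not passed), where the synthesis list went to -0.0144 and the matrix list to 0.189. These 3 calls are at the preset correlation. With Adipoq the clock list did not pass with an estimated correlation (adjusted p = 0.315) or by fry (adjusted p = 0.0869), and the other lists are reported at the preset correlation only. Muscle Sgms1 passed with median scaling (-0.80, where the median of all muscle differences was -0.05) and with trend and robust options (-0.70). In testis 1 probe passed without detection filter and 39 in 1 fit over all arrays, and the 1 list became 0 with an estimated correlation, by fry, with joint normalization and without filter, and 0 to 3 when 1 library was left out. In brain, leaving out 1 library gave 0 to 5 probes and 0 to 2 lists, and leaving out both in doubt gave 6 probes, 2 lists and Sgms1 at -1.71, and exchanging their labels 5, 2 and -1.65. Brain minus muscle gave 0 probes with the authors' values, 1 without both mice in doubt, 14 with the 2 brain libraries exchanged and 0 to 4 without 1 mouse. Without the mouse as replicate block it gave 4, of which 2 were shared. Testis minus muscle gave 16 with each tissue normalized by itself and 0 with the authors' values. Equal replicate numbers of the genotypes did not pair libraries (correlations of deviations -0.01 to 0.02 in testis, -0.01 to 0.14 in brain and 0.02 to 0.10 in muscle), and the replicate block gave 38 muscle probes, of which 10 were shared. The block ended the calls of Bhlhe40, Hp and the interferon and matrix lists. Leaving out 1 library, Sgms1 ran from -0.81 to -0.64 in muscle, -0.86 to -0.45 in testis and -1.30 to -0.45 in brain. The slide block was not run, since the tables used here give no slide. Probes near background, such as Cdsn and Taf6 in muscle, have folds that depend on the background step (Taf6 0.40 and Cdsn -0.52 without it).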

Other observations

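The counts over other splits of probes past the threshold were chosen after the results were seen, and those of gene lists were planned. The genes and lists here belong to lists fixed before, apart from Rbp7, which the naming rule took, and Hspb7, Rab6b and Cidea, named after their values were seen.

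In muscle, Asns and Gsta3 had larger differences than their lists, and neither the lists nor the genes over all probes passed, while each gene fell when adjusted over its list alone. Asns, encoding asparagine synthetase, differed by -1.03 (SE 0.18, adjusted p = 0.0687) in the list of endoplasmic reticulum stress genes (adjusted p = 0.844), and all 4 mutants lay below all 3 wild-type mice. Gsta3, a glutathione transferase gene, differed by -1.20 (SE 0.31, adjusted p = 0.224) in the list of oxidative stress genes, of which 12 of 15 were lower (adjusted p = 0.124). Muscle atrophy genes (adjusted p = 0.646), glycolysis genes (0.646) and satellite cell genes (0.844) did not pass. The brown fat gene Cidea was at 8.45 and 8.37 in wild types 1 and 3 and between 4.58 and 5.85 in the other 5 libraries. Without wild types 1 and 3, which leaves 1 wild-type library against 4 mutants, 4 probes passed, Lep (-2.93), Rbp7 (-1.81), Hspb7 (2.96, SE 0.31, adjusted p = 0.0255), encoding a small heat shock protein of muscle, and Rab6b (1.87, SE 0.17, adjusted p = 0.0128).

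In brain, cell type lists did not pass: astrocytes (adjusted p = 0.340, 10 of 13 higher), oligodendrocytes and myelin (0.50, 12 of 19 lower), microglia (0.50) and neurons (0.919). The pituitary hormone subunit gene Cga was at 9.79 and 7.05 and Pomc at 10.05 and 6.65 in the libraries labelled wild type 2 and wild type 3, while the other 5 lay between 4.28 and 5.02 for Cga and between 4.42 and 4.98 for Pomc. In testis the list of the blood-testis barrier (adjusted p = 0.702) did not pass, nor did the X-linked genes of spermatids (0.345).

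Other splits of the same libraries into groups of these sizes were counted for each result. For the 12 muscle probes 1 of 35 splits gave as many, the real one, and the highest other gave 1. This is the smallest share that 35 splits allow, for a count chosen after the result was seen, so it does not exclude chance. For the 6 muscle lists 8 of 35 splits gave as many, and the highest other gave 8. For the 1 testis list 31 of 35 did, with 9 as the highest other, so chance stays open for both. For the 0 probes of testis in limma (692 at an unadjusted p under 0.05) and the 0 probes and 0 lists of brain (586 probes and 2 lists at an unadjusted p under 0.05), all 35 of 35 splits give as many by definition, which says nothing about chance. The highest other split gave 2 probes in testis, and 8 probes and 5 lists in brain. In brain the real split is that of the labels, and the split with the labels of the 2 libraries in doubt exchanged gave 5 probes and 2 lists. How high the highest of 34 splits lies by chance was not tested.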
